A study of Mus musculus with 2 samples.

How the data were processed

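Gene expression was measured by RNA sequencing in 2 mouse livers, 1 library per genotype. Per the labels' protocols, livers were flash frozen, RNA was purified with an RNeasy Plus Mini kit and libraries followed the usual Illumina procedure. The values deposited by the authors are FPKM, fragments (or reads) scaled by transcript length and by the library's total, 1 column per library, per the file headers. The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.2 and the mouse build mm8, with no role or order. The counting tool, the annotation and any treatment of reads that match several genes are not given in the sources used here, nor is strand, so genes with close copies or overlapping genes are uncertain. Sex is not given by the labels.

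The deposited tables hold 35275 Ensembl gene IDs, of which 34490 (97.8%) matched a symbol of GENCODE M21; the 785 others kept their ID. Values of the 3 symbols carried by more than 1 ID were summed. No coordinates are in the deposited tables; those printed are GRCm38 positions of GENCODE M21.

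Depth was recovered from the values. FPKM that come from whole reads are whole multiples of 1 read's worth, which depends on gene length. From 478 genes with 1 read in each library the ratio of totals was 0.9512, and annotated lengths gave totals of 27919645 and 29351163 reads. At the rounded mean length of a gene's annotated transcripts, 8666 of 16964 genes with values above 0 in both libraries (51.1%) came out whole in both, and 0 did after each value was moved by up to 0.1%. A value was called whole within the rounding of its printed decimals. Those lengths belong to GENCODE M21 on GRCm38, a later build than the mm8 named in the notes, and this difference was not resolved. Whole reads were assigned to 82.6% of expressed genes; for the others, intervals rest on reads estimated from the annotated length. Whether the unit counted was a read or a fragment is not known. Counting error alone was 11.5% for a gene at an FPKM of 1 to 2 (median 75 reads), 4.0% at 10 to 20 and 1.5% at 100 to 200. In a gene of 2000 bases the floor of 3 reads is an FPKM of 0.0537 in the library labelled wild type and 0.0511 in the other. No count model was used.

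The comparison was the library labelled LTsc1KO against the library labelled wild type, as log2((FPKM + 1)/(FPKM + 1)) with a pseudocount of 1. Genes with an FPKM of at least 1 in at least 1 library were called expressed, and a log2 ratio of 1 or more, or -1 or less, counted as 2-fold. These ratios understate the difference of low genes; folds with intervals are ratios of FPKM without the pseudocount. Lists were described by the median of their expressed members and its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression; a list of at least 5 members stood apart at a percentile of 2.5 or less or 97.5 or more. Percentiles describe these libraries and are not tests.

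Named genes followed a rule fixed before the data were examined. It took 15 genes of the study's subject (Tsc1, Tsc2, Mtor, Rptor, Stat3, Socs3, Il6ra, Afp, Gpc3, Igf2, H19, Mki67, Ccnd1, Glul and Alb) and the 12 highest and 12 lowest log2 ratios among named genes with an FPKM of at least 10. From each list it took the 4 members with the largest absolute log2 ratio, the largest opposite member of at least 2-fold, and any sex chromosome gene or member of a list with under 5 expressed genes. Some genes that this rule names are not reported here.

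Alternatives planned beforehand were pseudocounts of 0.1 and 5, no filter or a minimum of 5, equal totals, the median ratio set to 0, upper quartile scaling, a 4-fold limit, the highest row per repeated name and list means. Removal of trends over gene length or GC content, matching of random lists on either, and removal of a list of skeletal muscle genes were added after the data were seen.

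In simulated data for this comparison (20350 genes, 200 changed, 50 per fold and direction), both totals and all recovered reads equalled the simulated ones. Every simulated gene had its rounded annotated length, so reads assigned at another length, as for 28.0% of genes above 0, were not checked. The simulated libraries differed only by the set folds and counting noise, and 3 of 10486 unchanged genes passed 2-fold. That share covers no difference between animals, so it is not an error rate for the counts below. The 2-fold limit was passed by 92% of genes simulated 2.8-fold higher and 66% simulated 2.8-fold lower, and by 100% and 90% at 8-fold. Of 100 random lists of 20 genes 3 stood apart, and 99 did after 1 was added to each log2 ratio. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.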

Results

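RNA sequencing measured gene expression in 2 livers of C57BL/6 mice aged 10 months: 1 library labelled wild type and 1 library labelled LTsc1KO, a liver-specific knockout of Tsc1. Tsc1 encodes hamartin, a subunit of the complex that restrains the growth kinase mTORC1. The series describes a mouse model in which liver cancer arises without inflammation and asks for its molecular basis. Its text speaks of tumour tissue, while the labels of both samples say liver, so whether a nodule was sampled is not known here. The deposited values are FPKM for 35275 genes. The total numbers of reads recovered from these values were 27919645 in the library labelled wild type and 29351163 in the library labelled LTsc1KO. With 1 library per genotype there is no replicate check of any difference, no p-value is given, and a difference between these libraries may be one between animals. Intervals below are 95% exact binomial (Clopper-Pearson) intervals on reads and cover counting error only.

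Tsc1 (ENSMUSG00000026812; chromosome 2, 28641228 to 28691167, plus strand, GRCm38 in GENCODE M21) had nearly equal values, with an FPKM of 4.90 (570 reads) in the library labelled wild type and 4.79 (585 reads) in the library labelled LTsc1KO. The ratio was 0.976 (interval 0.868 to 1.10), a log2 ratio of -0.03. Its direction depends on the scaling: Tsc1 stood at -0.59 with the median ratio set to 0, as described next, and at 0.12 with both libraries rescaled to equal totals. The targeted gene therefore does not check the labels. Which exons were deleted is not given in the sources used here, and a value summed over the whole gene includes exons outside a deletion and cells other than hepatocytes. Both libraries are named by their label throughout, and every direction below depends on those labels.

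Among 12395 expressed genes (an FPKM of at least 1 in at least 1 library), 4411 (35.6%) were at least 2-fold higher in the library labelled LTsc1KO and 762 (6.15%) were at least 2-fold lower, on the scale of log2(FPKM + 1). The median log2 ratio of expressed genes was 0.70. With the median ratio of genes at an FPKM of at least 1 in both libraries set to 0, 11851 genes still counted as expressed. Of these 1848 were at least 2-fold higher and 1504 lower. The share of higher genes among 2-fold genes went from 85.3% to 55.1%. List counts given below for this scaling likewise leave out members that no longer counted as expressed. The 10 most abundant genes took 25.7% of reads in the library labelled wild type and 11.9% in the other. Serum amyloid A genes Saa1 and Saa2 alone took 9.91% and 0.02%. Across expressed genes Pearson's r was 0.833 and Spearman's rho 0.814, where genes are not independent replicates. Of 54 gene lists fixed before the data were examined, 47 had at least 5 expressed members. Compared with 10000 random lists matched on expression, 11 stood apart as higher and 13 as lower, where chance would set 2.4 apart if genes were independent. Genes of a list can vary together between animals and some lists share members, so the 2.4 is not a test. The medians of these random lists ran from 0.02 for lists matched to cytosolic ribosomal proteins to 0.78 for lists matched to proliferation genes, so each list is to be read against its own random lists. With the median ratio set to 0 the positive medians of mTORC2, AKT and insulin signalling, the JAK-STAT3 list, male-biased genes, sinusoidal endothelial markers and stellate cell markers turned negative, as did others named where they occur.

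**Figure D1:**
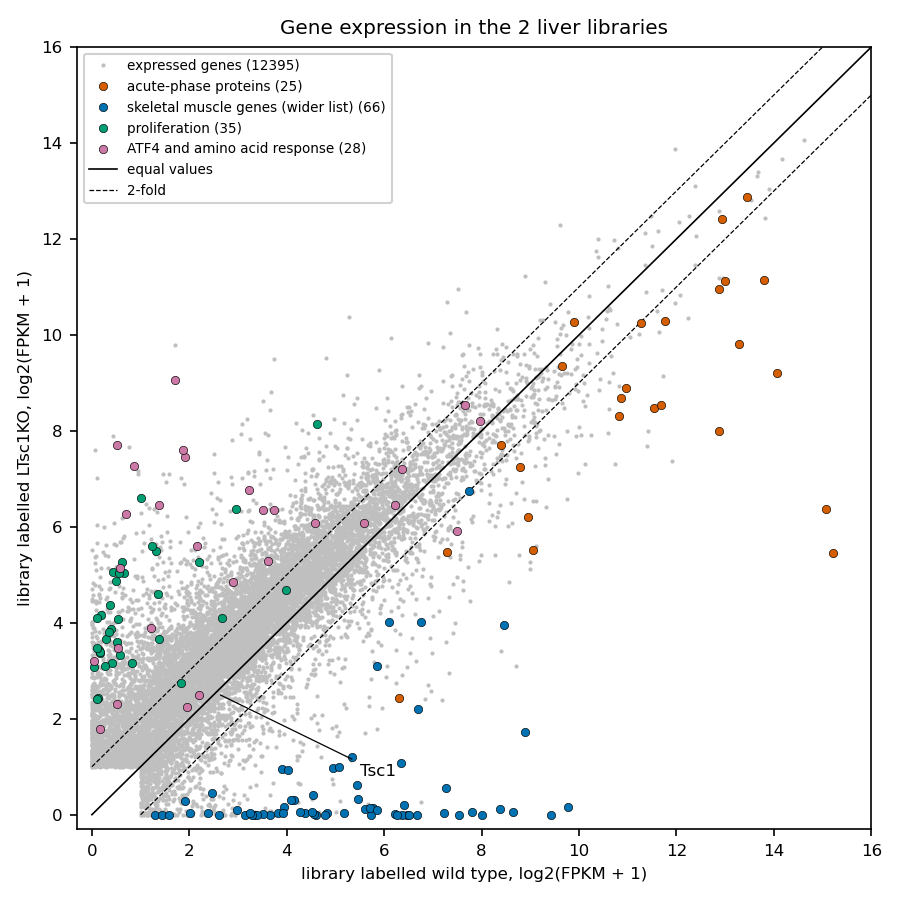
Each point is 1 of 12395 expressed genes, with log2(FPKM + 1) in the library labelled wild type on the x axis and in the library labelled LTsc1KO on the y axis. Acute-phase genes (25) lie mostly below the line of equal values and proliferation genes (35) above it; the 66 skeletal muscle genes, a list written after muscle genes were seen among the lowest ratios, lie mostly near the bottom.

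Genes with the highest log2 ratios were led by Tff3, a secreted trefoil peptide, at an FPKM of 2.25 in the library labelled wild type and 880 in the library labelled LTsc1KO (391-fold higher, interval 275 to 575). Next came Bex2, Ubd, the stress-response gene Nupr1 (2.28 and 534), Psat1 (0.436 and 206), Rnase1, Pfkp and Phgdh (0.829 and 154). Psat1 and Phgdh encode enzymes of serine synthesis. Gipc2, Gsta1, Hkdc1 and Ly6d complete the 12 highest. At the low end stood Saa2 (884-fold lower, interval 841 to 931) and Saa1 (423-fold lower, interval 410 to 437), which are close copies that can share reads. The remaining 10 of the 12 lowest genes encode proteins abundant in skeletal muscle: Acta1 was at 875 and 0.119, Tnni2 at 401 and 0.0469, and Tnnt3, Mb and Myl1 had no reads in the library labelled LTsc1KO. Set at the floor of 3 reads there, Mb, myoglobin, would be 2621-fold lower. The interval for Mb reaches down to 2131-fold lower. The others are Atp2a1, Tcap, Ckm, Mylpf and Des.

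The TSC and mTORC1 list also holds regulators and substrates outside these complexes, such as Rragd and Eif4ebp1. Of its 21 genes 10 were at least 2-fold higher in the library labelled LTsc1KO and none lower, or 5 and 1 with the median ratio set to 0. Their median of 0.98 lay within the random range (percentile 93.3). Mtor, the kinase itself, was 3.82-fold higher (interval 3.51 to 4.17). Tsc2, the partner of Tsc1, was 2.36-fold higher (2.01 to 2.78) and Rptor 1.92-fold higher (1.73 to 2.12). Rragd, a GTPase that recruits mTORC1 to lysosomes, had the highest ratio of the list (log2 ratio 3.98). For mTORC2, AKT and insulin signalling the median was 0.68 (percentile 62.3), with Grb10 at 4.26 and Igf1 at -2.51.

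Targets of ATF4, the transcription factor of the amino acid response, were much higher in the library labelled LTsc1KO: 20 of 28 were at least 2-fold higher and 1 lower (median 2.64, above all 10000 random lists). Nupr1, Psat1, Phgdh and Trib3 led, with log2 ratios of 7.35, 7.17, 6.40 and 5.72, and Cebpb went the other way at -1.58. Aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, were higher by at least 2-fold in 13 of 18 cases and lower in none (median 1.38, percentile 99.98), or in 6 with the median ratio set to 0, with Gars at 2.82 and Sars at 2.61. Ribosome biogenesis (median 0.98, percentile 91.0) and nucleotide synthesis (median 1.01, percentile 84.6) stayed within the random range, although Nhp2 stood at 2.18 and Ctps at 2.82. So did the cytosolic ribosomal proteins (median -0.02, percentile 43.2), where 33 of 35 members lay between the 2-fold limits; with the median ratio set to 0, 11 were at least 2-fold lower and none higher.

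**Figure D2:**
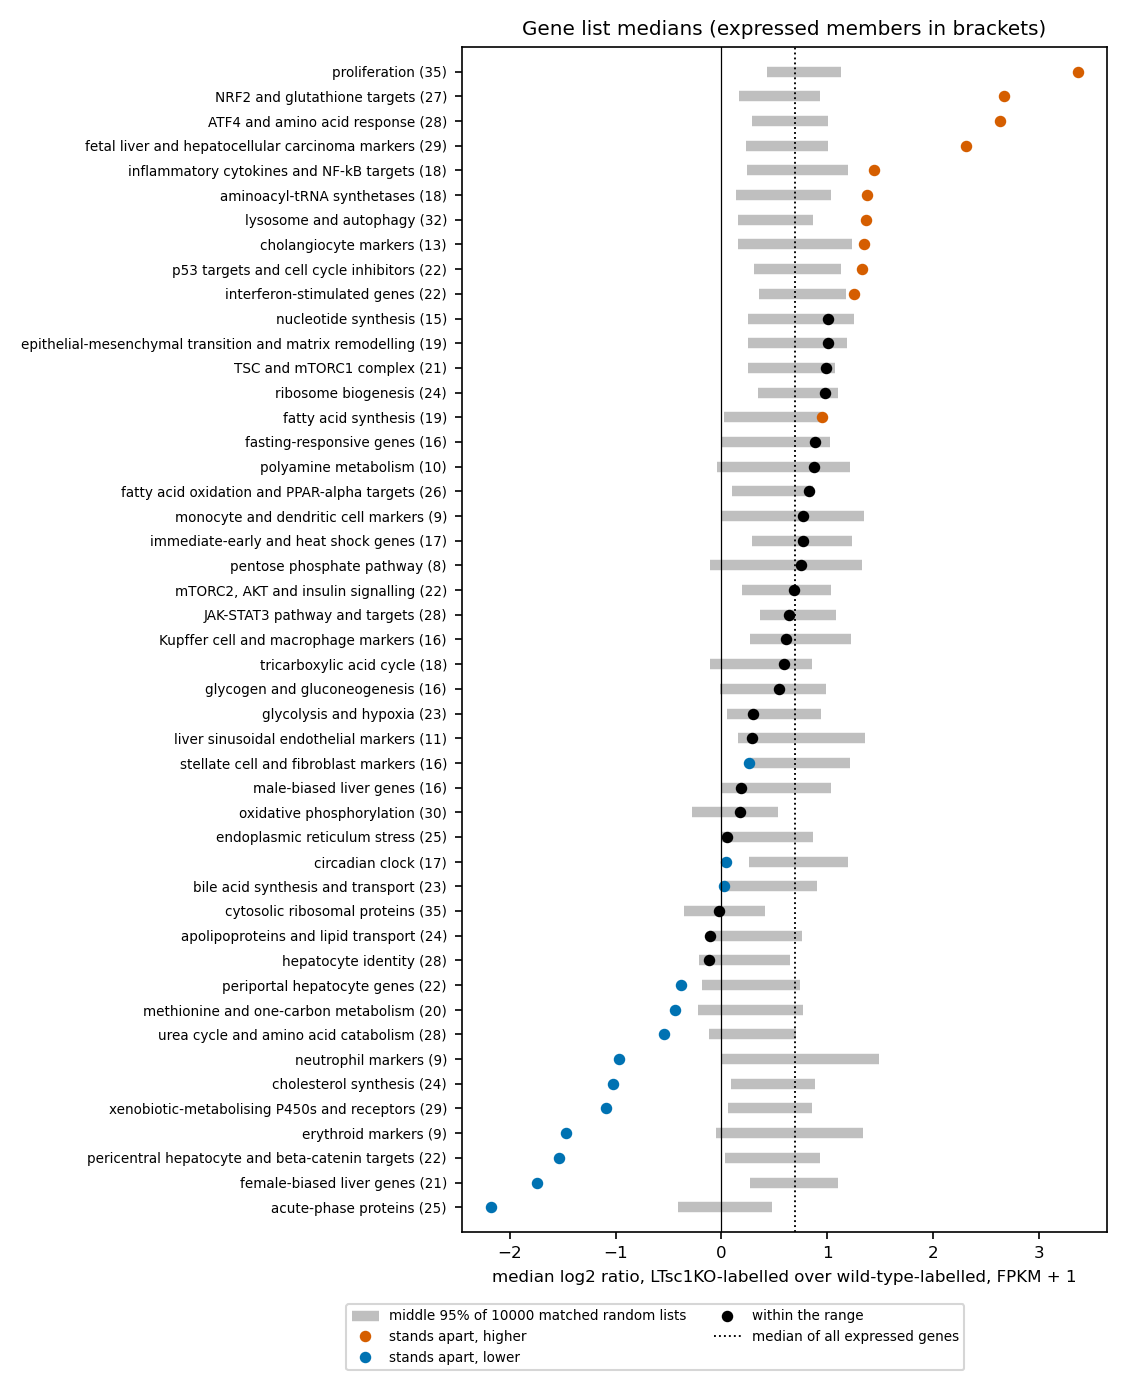
Each point is the median log2 ratio, library labelled LTsc1KO over library labelled wild type, of the expressed members of 1 of 47 gene lists, and each grey bar spans the middle 95% of 10000 random lists matched on expression. Coloured points lie outside the bar (11 higher, 13 lower), and the dotted line marks the median of 0.70 over all expressed genes.

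Proliferation genes formed the list with the highest median. In the library labelled LTsc1KO, 33 of 35 were at least 2-fold higher and none lower (median 3.37, above all 10000 random lists), and 32 still were with the median ratio set to 0. Mcm6, part of the replicative helicase, was at 1.02 and 96.0, Cdk1, the mitotic kinase, at 0.532 and 37.5, and Mki67 at 0.128 and 9.41. Fetal liver and hepatocellular carcinoma markers were higher in 22 of 29 cases and lower in 2 (median 2.31, above all random lists). Besides Tff3 these included Ly6d (12.4 and 718), Cd63 (11.7 and 450), Golm1 (0.405 and 48.2) and Gpc3, glypican 3, which was 85.6-fold higher (interval 53.3 to 147). H19 was 6.00-fold higher (5.77 to 6.24). By contrast Afp, alpha-fetoprotein, was at 1.80 and 2.53 (ratio 1.40, interval 0.95 to 2.07) and Igf2 at 0.663 and 0.358, and Lgr5 stood at -1.57. Ccnd1, at 2.55 and 5.73, was 2.24-fold higher (1.85 to 2.74). Afp was low in both libraries and its ratio lay below that of the median gene.

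Inhibitors of the cell cycle and p53 targets were also higher, in 14 of 22 cases, with 1 lower (median 1.33, percentile 99.8), or 8 and 1 with the median ratio set to 0. Cdkn1a, which encodes p21, had the highest log2 ratio of the list and was 43.5-fold higher by FPKM (interval 35.2 to 54.2). Next by log2 ratio came Eda2r (3.46) and Pmaip1 (3.36), while Gadd45g stood at -1.30. Targets of NRF2, the regulator of the oxidative stress response, were higher in 22 of 27 cases and lower in none (median 2.67, above all random lists). Among them Gsta1 and Gsta2 had log2 ratios of 6.16 and 5.11, although these glutathione transferase genes are similar in sequence and can share reads, and Gpx2 stood at 5.26. Lysosome and autophagy genes were higher in 18 of 32 cases and lower in 1 (median 1.37, above all random lists), or 12 and 1 with the median ratio set to 0. Sqstm1, which encodes the autophagy receptor p62, was 10.9-fold higher (10.6 to 11.2), and Gpnmb stood at 4.81 and Atp6v0d2 at -1.40. Endoplasmic reticulum stress genes did not stand apart (median 0.05, percentile 4.31, but 2.20 when matched on gene length, which makes the list stand apart as lower); Atf3 and Ddit3 were at 3.03 and 2.84, and the list's median turned negative, -0.63, with the median ratio set to 0.

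Genes of acute-phase proteins, which the liver makes in response to IL-6 through STAT3, were lower in the library labelled LTsc1KO as a group. Of 25 expressed members 20 were at least 2-fold lower and none higher (median -2.18, below all 10000 random lists). After Saa1 and Saa2 the largest differences were in the metallothioneins Mt2 and Mt1, with log2 ratios of -4.90 and -4.85. Stat3 itself was 2.02-fold lower (interval 1.94 to 2.10), at 149 and 74.0, and Socs3, a STAT3-induced feedback inhibitor, was 12.2-fold lower (10.7 to 13.9), at 99.3 and 8.14. Il6ra was at 7.15 and 8.13. The JAK-STAT3 list as a whole was divided, with 9 of 28 members at least 2-fold higher and 7 lower (median 0.63, percentile 32.4), or 2 and 8 with the median ratio set to 0. Junb and Pim1 were at -2.40 and -2.15 and Myc at 2.11.

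Of 27 inflammatory cytokines and NF-kB targets only 18 were expressed, and these stood apart as higher (median 1.44, percentile 99.8). Of the 18, 13 were at least 2-fold higher and 1 lower, or 8 and 1 with the median ratio set to 0. Ccl2, a monocyte chemokine, was at 0.30 and 9.24 and Tlr2 at 1.37 and 12.2, whereas the neutrophil chemokine Cxcl1 was 6.44-fold lower (interval 6.10 to 6.79). Interferon-stimulated genes were higher in 15 of 22 cases and lower in 1 (median 1.25, percentile 99.0), or 7 and 1 with the median ratio set to 0, with Usp18 at 3.86, Ifit2 at 3.84 and Mx2 at -1.81.

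**Figure D3:**
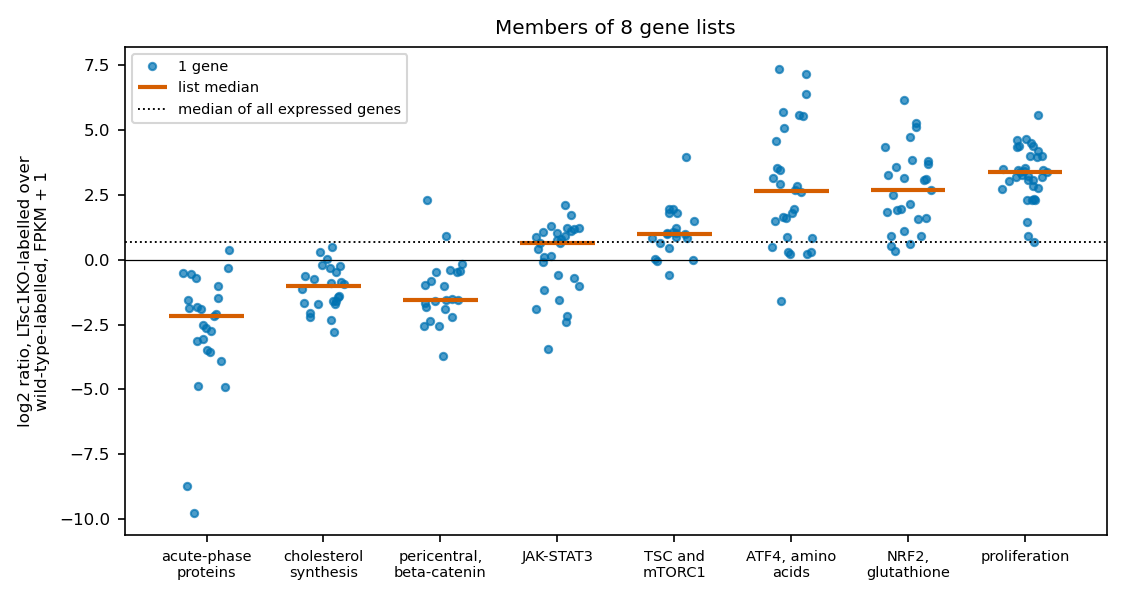
Each point is 1 expressed gene of 8 gene lists, with its log2 ratio (library labelled LTsc1KO over library labelled wild type) on the y axis; orange bars are list medians and the dotted line is the median of 0.70 over all expressed genes. Medians run from -2.18 for acute-phase proteins to 3.37 for proliferation, and members of the JAK-STAT3 list lie on both sides of 0.

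Lipid genes divided by pathway. No cholesterol synthesis gene was at least 2-fold higher and 12 of 24 were at least 2-fold lower (median -1.02, below all random lists), or 19 with the median ratio set to 0, among them Tm7sf2 (-2.80), Idi1 (-2.30) and Fdft1 (-2.20). Fatty acid synthesis genes were higher in 8 of 19 cases and lower in 1, or in 5 and 2 once the median ratio was set to 0. Their median was 0.95 on the deposited scale (percentile 97.7; 96.8 once random lists were also matched on gene length, which ends the call). Fads2, a desaturase, stood at 3.18, while Thrsp stood at -1.61. For fatty acid oxidation and PPAR-alpha targets the median was 0.83 and within the range, with Cidec, a lipid droplet protein, at 4.25 and Pdk4 at -1.57. Apolipoproteins and lipid transport genes had a median of -0.11 (percentile 2.71; 0.630 when matched on gene length, which makes the list stand apart), with Apoa4 at 3.19 and Fabp4 at -2.57.

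Central carbon metabolism did not stand apart. Medians were 0.30 for glycolysis and hypoxia, 0.75 for the pentose phosphate pathway, 0.59 for the tricarboxylic acid cycle, 0.18 for oxidative phosphorylation and 0.54 for glycogen and gluconeogenesis; of these only the pentose phosphate median, 0.07, stayed positive with the median ratio set to 0. Single genes differed by more: Pfkp, the platelet-type phosphofructokinase, was at 0.684 and 201 while the muscle form Pfkm was at 29.4 and 8.34, and Pgd was at 18.6 and 96.4. Pfkm is also expressed in skeletal muscle, and the 66 skeletal muscle genes of the scatter figure were all at least 2-fold lower in the library labelled LTsc1KO. Polyamine metabolism had a median of 0.88 (percentile 83.1), with Sat1 at 1.97 and Paox at -2.10.

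Lists of differentiated hepatocyte functions differed in how far they stood from random lists. Pericentral genes and beta-catenin targets were at least 2-fold lower in 13 of 22 cases and higher in 1 (median -1.54, below all random lists): Oat was 13.5-fold lower (interval 12.7 to 14.2), Cyp2e1 stood at -2.57 and Glul, glutamine synthetase, was 3.0-fold lower (2.94 to 3.06), while Aldh3a2 stood at 2.29. Xenobiotic-metabolising P450s and receptors were lower in 18 of 29 cases and higher in 2 (median -1.09, below all random lists), led by Cyp2c54 and Cyp2c40, members of a family whose copies can share reads, with Cyp2b10 the other way at 2.02. Periportal genes stood apart as well (median -0.38, percentile 0.320), but in both directions, with Aldh1b1 at 3.24 and Rnase4 at -2.16. The median for urea cycle and amino acid catabolism was -0.55 (percentile 0.0200), with 5 of 28 members at least 2-fold lower and 1 higher, or 16 and 1 with the median ratio set to 0. Agxt and Arg1 stood at -2.26 and -2.12 and Gldc at 2.15. For methionine and one-carbon metabolism it was -0.43 (percentile 0.290), with 5 of 20 lower and 2 higher, or 11 and 1 with the median ratio set to 0; Nnmt and Gnmt stood at -2.86 and -2.64. Bile acid genes had a median of 0.03 (percentile 2.48) that was -0.62 with the median ratio set to 0. Of 23 members 7 were at least 2-fold higher and 1 lower, or 5 and 7 with the median ratio set to 0, with the exporters Abcc4 and Abcc3 at 3.56 and 3.07 and Slc27a5 at -1.85. Hepatocyte identity genes did not stand apart (median -0.12, percentile 5.63); matched on gene length they did (percentile 0.75). Alb, albumin, was 2.59-fold lower (2.58 to 2.61) and Apob stood at 2.06.

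Xist, transcribed from the inactive X chromosome, had an FPKM of 76.0 in the library labelled wild type and 165 in the library labelled LTsc1KO, and the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0.0488 and 0.292. Female-biased liver genes were lower in 14 of 21 cases and higher in 2 (median -1.74, below all random lists). Sult3a1, a sulfotransferase, was 548-fold lower (interval 252 to 1495), and Cyp2c40, A1bg and Cyp3a44 stood at -4.38, -4.30 and -4.19, while Cyp4a14 stood at 1.49. Male-biased genes went both ways (6 of 16 higher and 5 lower; median 0.18, percentile 7.34), or 4 and 5 with the median ratio set to 0, with Cyp2d9 at 4.08, Mup20 at 3.58, Mup1 at -4.43 and Serpina1e at -3.86.

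Lists that follow the handling or hour of sampling were also examined. Circadian clock genes had a median of 0.04 (percentile 0.320), which was -0.62 with the median ratio set to 0; Arntl stood at 2.29 and Dbp, which peaks in the opposite phase, at -1.45. The median of fasting-responsive genes was 0.89 (percentile 92.3), with Fgf21 at 5.57 and Igfbp1 at 2.61. Immediate-early and heat shock genes had a median of 0.77 (percentile 54.6). The hour of sampling and feeding state are not given in the sources used here.

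Markers of other cell types differed in several directions. Cholangiocyte markers were higher in 8 of 13 cases and lower in none (median 1.34, percentile 99.1), or 4 and 1 with the median ratio set to 0, with Cldn7 at 4.71 and Spp1, osteopontin, at 36.9 and 575. Neutrophil markers were lower (median -0.97, below all random lists), with 4 of 9 at least 2-fold lower, or 7 with the median ratio set to 0. Erythroid markers were lower in 5 of 9 cases and higher in 1 (median -1.47, below all random lists). The globin genes Hbb-bs and Hba-a2 stood at -3.72 and -3.46 and can share reads with their copies, while Tmem56 was 3.22-fold higher (3.05 to 3.41). Stellate cell and fibroblast markers had a median of 0.26 (percentile 2.17; 2.70 when matched on gene length, which ends the call) with members far apart: Col4a1 stood at 4.33 and Des, also a muscle gene, at -6.71. Kupffer cell and macrophage markers (median 0.61, percentile 27.6), monocyte and dendritic cell markers (median 0.77, percentile 58.7) and sinusoidal endothelial markers (median 0.29, percentile 6.03) did not stand apart. Of 18 monocyte and dendritic cell markers 9 were expressed, with 4 at least 2-fold higher and 1 lower. With the median ratio set to 0, those that still counted as expressed had a median of 1.56. Within the Kupffer list Cd68 was at 1.32 and 52.3 and Marco at 3.37 and 0.505, within the monocyte list Cd74 at 12.1 and 146 and Ly6c1 at 6.99 and 1.92, and within the endothelial list Flt4 at 0.255 and 40.7. Genes of the epithelial-mesenchymal transition and matrix remodelling had a median of 1.00 (percentile 88.3), with Cd44 at 4.10.

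Few members of the remaining lists were expressed. Among T and NK cell markers 1 of 21 was (Nkg7, 1.02 and 0.815), and among B cell and plasma cell markers 1 of 14 (Jchain, 14.2 and 5.46). For platelet markers the count was 2 of 9 (Pf4, 1.47 and 2.15), for exocrine pancreas 3 of 18, for adipocytes 4 of 10 (Lpl, 54.8 and 83.0) and for mesothelium 1 of 8 (Krt8, 119 and 904, a keratin that hepatocytes also express). Of the exocrine pancreas genes Cela1 was at 7.5 and 14.5, and Prss2 and Sycn had no reads in the library labelled wild type and FPKM of 2.22 and 2.57 in the library labelled LTsc1KO. Set at the floor of 3 reads in the library labelled wild type, these would be 16.8-fold and 13.3-fold higher, which is not a lower bound.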

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

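The trend corrections, the matching on length or GC content and the removal of muscle genes were chosen after the data were seen. Against 4411 genes higher and 762 lower, a pseudocount of 5 gave 2225 and 459, the median ratio set to 0 gave 1848 and 1504, and upper quartile scaling gave 2067 and 1602. The 4-fold limit, stricter by construction, gave 1098 and 283. The median log2 ratio of expressed genes, 0.70, was 0.07 and 0.08 under these scalings, 0.42 with a pseudocount of 5, 0.22 with no filter, 0.75 at a minimum FPKM of 5, 0.82 with a pseudocount of 0.1 and 0.84 with equal totals, which gave 5251 and 647; why it lies above 0 was not tested. The other alternatives left both counts within 1.5 times, and without the listed muscle genes 696 were lower. Lists standing apart numbered 9 to 12 higher and 12 to 19 lower over all alternatives run. Tsc1 went from -0.03 to -0.59 with the median ratio set to 0 and 0.12 with equal totals, and Pearson's r from 0.833 to 0.906 with no filter and 0.771 with a pseudocount of 0.1.

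With the median ratio set to 0, list medians turned negative for bile acid genes (-0.62), circadian clock genes (-0.62) and stellate cell markers (-0.28). Removal of the GC trend gave -0.0079 for bile acid genes and -0.021 for clock genes, and removal of the length trend gave -0.056 for clock genes. At a minimum FPKM of 5 clock genes were at -0.14 and stellate cell markers at -0.45, with no filter the latter were at -0.038, and the mean of clock genes was -0.057. The cause was not tested. Of the other list medians under an alternative, 304 moved by less than the spread of random lists. The other 169 moved by more or belonged to the 7 lists with under 5 expressed members, which have no random lists. None of these was a change of sign in a list that stood apart. No named gene past 2-fold changed sign. Over all named genes but Tsc1, 679 values under an alternative stayed within the counting interval and 529 did not. Depth limits genes near an FPKM of 1, where counting error is 11.5%.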

Other observations

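Gene families, the muscle and negative acute-phase lists, and the tests of scaling, of negative acute-phase genes, of sex and of shared reads were chosen after the results they concern were seen. Predictions for the share of the muscle list, and for gene length, were written before those values were seen. Among 299 families defined by the letters that start a symbol (at least 6 expressed genes), 31 stood apart as higher and 22 as lower. Chance would set 14.9 apart if genes were independent, which members of a family need not be. Nucleoporin genes were higher in the library labelled LTsc1KO, with 18 of 19 symbols that start with Nup at least 2-fold higher (median 1.71, and 1.06 with the median ratio set to 0). Genes named Casp, mostly caspases, were higher in 8 of 10 cases (median 1.76), among them Casp1 (4.65), Casp12 (3.90) and Casp4 (3.81), named after their values were seen. Genes named Col were higher in 11 of 19 cases and lower in none, led by the basement membrane collagens Col4a1 (4.33) and Col4a2. On the low side were the carboxylesterases (7 of 12 lower, 4 higher), sulfotransferases (10 of 15 lower), genes named Serpina (9 of 14 lower) and major urinary proteins (13 of 17 lower, with Mup20 higher at 3.58). Members of these low families are close copies that can share reads.

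Skeletal muscle genes were detected in the library labelled wild type. The wider muscle list, which holds the genes that drew attention, had all 66 expressed members at least 2-fold lower in the library labelled LTsc1KO, with Acta1 at 875, Tnnt3 at 690 and Mylpf at 475 in the library labelled wild type. Scaling is argued against, since a factor common to a library moves all its genes alike. Of 30 other muscle transcripts, listed before their values were read, 28 were expressed. Their median was -3.72, or -4.46 relative to random lists matched on expression, none of which lay as low. A candidate explanation is skeletal muscle tissue in that sample. Of the 30, 66.7% were at least 8-fold higher in the library labelled wild type, short of the 80% set before the test. The 10 others missed 8-fold, and 8 of them had an FPKM under 7 there, where a pseudocount of 1 puts it out of reach. The 80% could therefore not have been met, and the test cannot decide. By FPKM 29 of 30 were higher there, and 4 reached an FPKM of 1 in the other library. Muscle tissue is left undecided, and genotype was not tested.

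Acute-phase genes were lower in the library labelled LTsc1KO. A scaling factor does not account for this: the list's median was -2.21 relative to random lists matched on expression, all of which lay higher. With the length trend removed the median was -2.20. That trend is small, with median log2 ratios of 0.27 among the shortest genes and 0.80 among the longest. Its removal could hardly have lifted the list, so that test cannot decide. Random lists also matched on gene length all lay higher too, which argues against gene length as the whole cause. An acute-phase response in the animal labelled wild type may have raised them in its library, and it would lower negative acute-phase genes such as Alb and Ttr in the same library. Relative to all expressed genes those had a median of -1.70, the opposite direction, and they also stood apart as lower from random lists matched on expression. By that comparison with all genes 4 of 16 lay above and 12 below, short of the share required. A response of that animal and an effect of genotype cannot be told apart with 1 animal each, and which is the case stays open.

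Female-biased genes were lower in the library labelled LTsc1KO although both libraries hold Xist, whose lower FPKM was 76.0, with Y-linked genes near 0, which argues against animals of different sex. With the length trend removed the list lay at -2.38 relative to all expressed genes, but that trend is too small for its removal to decide. Random lists also matched on gene length all lay higher than the list, which argues against gene length as the whole cause. Reads shared within the Cyp, Sult and Mup families are also argued against as the whole cause. The list's 8 members outside those families lay at -1.78 relative to all expressed genes, with 6 of 8 below. One hypothesis, untested here, is that the sex-biased programme of the liver differs with genotype; age and strain are equal by label, and with 1 animal each individual variation stays open.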
